A study of Mus musculus with 6 samples.

How the data were processed

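Skin of mice was profiled by RNA sequencing in 2 groups of 3 libraries, untreated controls (CON) and mice given imiquimod (MOD), a Toll-like receptor 7 agonist that produces psoriasis-like inflammation when applied to mouse skin. Per the series' design text, MOD mice received 62.5 mg of imiquimod on shaved back skin on each of 6 days. Per the labels' protocols, total RNA was extracted with TRIzol, DNA was removed with DNase I, and libraries were made with a SMARTER mRNA-Seq kit. The genome build was GRCm39, per the submitters' processing notes. The aligner, the gene annotation and the quantification program are not given in the sources used here, nor are strain, sex, age or sequencing batch. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

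The authors deposited 1 table of TPM values, length-normalized transcript abundances, for 57010 genes in the 6 libraries, with gene names, Gene Ontology terms and KEGG pathways beside each gene. TPM divides a gene's reads by its length and scales each library to a fixed total, so a value is a share of that library's RNA, and a rise of abundant transcripts lowers the rest. TPM keeps no sequencing depth. Depth is therefore unknown, and no counting interval or detection floor is given. Genes with near-identical copies, such as the Stfa, Saa, Sprr2a, Mup, Krtap, alpha-globin and Krt6 families and the retrocopies of ribosomal protein genes, can exchange reads, and their values are uncertain. No coordinates are given, because the supplied annotation (GENCODE M21) belongs to GRCm38. It was used only for gene types, which 52029 of the IDs matched. In the table, 1606 IDs had no symbol.

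Columns were assigned to samples by the column names that the labels give. Libraries are numbered here as in the labels' titles. The deposited columns of the controls are named otherwise: CON 1 is column CON1, CON 2 is column CON3 and CON 3 is column CON4. The 12 core genes checked (such as Actb, Gapdh and Eef2) were above 0 in all libraries. No gene is given a fold against a group listed at 0. Between 0.0653 and 1.02% of tested genes had identical values in a given pair of libraries, so no library holds the values of another.

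Values were analysed as log2(TPM + 1) for the 15323 genes with at least 1 TPM in at least 3 of the 6 libraries. A gene near 0 in a group met this filter through the other group, which largely fixed its direction. Differences are on the log2(TPM + 1) scale, which understates the change of low genes. Folds of mean TPM are given beside them as ratios of the 2 group means. MOD was compared with CON in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). "Rose" and "fell" are used for genes past this threshold. The 38 gene lists (23 pathways or families and 15 sets of cell type markers, 762 members, of which 705 were tested) were fixed before the data were examined. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists. Camera compares a list with all other genes. Estimated inter-gene correlations and fry, which asks whether a list's genes move in 1 direction on balance, were run as alternatives. Annotation terms with 10 to 300 tested members were tested for over-representation by Fisher's exact test (one-sided, Benjamini-Hochberg over terms), separately for genes at least 2-fold higher or lower. The background was the tested genes with any term of that annotation, 14719 for Gene Ontology and 5804 for KEGG.

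The genes named were chosen by a rule written before the data were examined. It takes the 8 genes with the largest rise and the 8 with the largest fall past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between groups, leaving out predicted genes and immunoglobulin or T cell receptor segments. It also takes up to 4 members of each list with the largest change (with 1 in the opposite direction, or the 2 most abundant where none passed), the 10 genes Jak1, Jak2, Jak3, Tyk2, Stat3, Il17a, Il17f, Il22, Il23a and Tlr7, and for an enriched term the 3 members with the largest change. Genes outside this rule are named as such.

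On simulated values with the means and spreads of the 15323 genes of the MOD against CON comparison, 200 genes were changed by known amounts. The procedure recovered 50% of those changed by 1 on the log2 scale, 82% of those changed by 2 and 98% of those changed by 3, with 5 of 161 calls made on genes that had not been changed. The changed genes were drawn from the more abundant ones in CON. In the data 7452 genes were called, which makes the Benjamini-Hochberg threshold less strict than in the simulation. The recovered shares therefore do not carry over to the data.

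Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, other filters on low values, median-of-ratios scaling, quantile normalization, leaving out the 20 most abundant genes, eBayes without the trend or in its robust form, array weights, the replicate number as a block, leaving out each library, limma's treat, and other term sizes or no fold threshold for terms. A further alternative was chosen after the data were examined. CON 1 and CON 3 expressed H2-Ea and the other libraries did not, so this split was added to the model as a term. MOD is then set against CON 2, and CON 2, the lone control on its side of the split, is assumed to vary like the other libraries. This fit is called the fit with the H2-Ea term. Figures were drawn with matplotlib 3.10.9.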

Results

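The comparison asked how imiquimod changed gene expression in mouse back skin, in a study whose title concerns a plant polysaccharide and JAK/STAT3 signalling in imiquimod-induced lesions. The data were TPM values per gene in 3 control (CON) and 3 imiquimod-treated (MOD) libraries. Polysaccharide-treated mice were not analysed here. Between 23311 and 24647 genes were listed above 0 in a library, and sequencing depth is unknown because TPM keeps none. Xist lay between 58.1 and 114 TPM and the Y-linked gene Ddx3y was listed at 0 in all 6 libraries.

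The groups separated along the first principal component, which held 73% of the variance of log2(TPM + 1). Pearson correlations across tested genes, which are not independent replicates, were 0.968 to 0.976 within MOD, 0.938 to 0.942 within CON and 0.775 to 0.879 between groups. The controls were not alike in all respects. H2-Ea, which encodes the alpha chain of the MHC class II molecule E, stood at 194 TPM in CON 1 and 162 TPM in CON 3 and was listed at 0 in CON 2 and in all MOD libraries. Its partner H2-Eb1 was present in all of them (194 to 531 TPM). The same pattern, above 15 TPM in CON 1 and CON 3 and below 1 TPM elsewhere, was found for 39 genes, 30 of them annotated as pseudogenes, against at most 5 genes for any other pair of libraries. Some abundant genes differed along the same split. Rps18 stood at 64.6 and 76.1 TPM in CON 1 and CON 3, 3622 TPM in CON 2 and 1954 to 2247 TPM in MOD, and Rpl3 at 447, 472, 1554 and 654 to 847 TPM. These genes were singled out after their values were seen. CON 1 and CON 3 form a side of this split with no MOD library, so no comparison can be made within it. On the other side, MOD can be compared with CON 2, and values from the fit with the H2-Ea term are given beside the pooled ones.

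**Figure D1:**
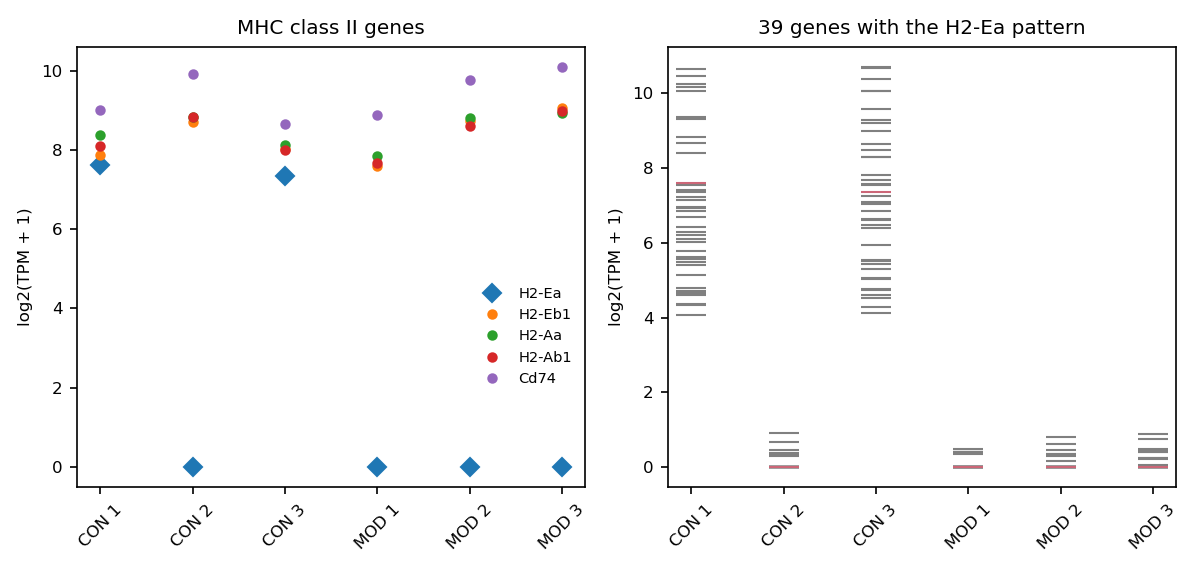
Expression per library of MHC class II genes (left) and of the 39 genes with the H2-Ea pattern (right, H2-Ea in red), as log2(TPM + 1), 1 mark per gene and library. H2-Ea was listed at 0 in CON 2 and all MOD libraries, where the other class II genes were expressed.

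In MOD, 1914 genes were higher and 5538 lower (limma, adjusted p below 0.05), of which 1140 were higher and 2052 lower at least 2-fold. Groups did not overlap for 59.5% of tested genes, where chance gives 10% for 3 libraries against 3. The balance between higher and lower depended on the scaling, since the median of all tested genes lay at -0.31. Higher genes made up 25.7% of the calls in TPM, 51.9% with median-of-ratios scaling (3097 higher and 2868 lower, median 0.00), 47.0% with quantile normalization (2818 and 3177) and 35.5% without the 20 most abundant genes (2314 and 4211). These 20 genes took 22.5 to 26.1% of MOD and 15.2 to 17.0% of CON values. With the H2-Ea term, 667 genes were higher and 2747 lower, 3300 of them among the 7452 calls of the pooled fit, and none of those 7452 had the opposite sign.

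The genes with the largest rise included acute-phase and alarmin genes. Saa3, a serum amyloid A protein, rose from 6.01 ± 5.28 to 4498 ± 2762 TPM (SD, n = 3 per group), a log2 difference of 9.38 (SE 0.75, limma adjusted p = 0.00087). S100a8 rose 120-fold in mean TPM, from 11.3 to 35.2 TPM in the CON libraries to 2799 ± 1279 TPM (log2 difference 6.86), and its partner S100a9 rose from 22.2 ± 14.2 to 2051 ± 1346 TPM (6.43). Saa1 (log2 difference 7.04) and Saa2 (6.57) are close copies of each other. Stfa1, a stefin, rose by 7.40, the small proline-rich gene Sprr2a2 by 7.03 and Rpl38-ps2, a ribosomal protein pseudogene, by 7.15. For these 3 genes CON 2 stood apart from the other controls. Stfa1 was at 28.7 TPM in CON 2 against 0 and 0.62 TPM, Sprr2a2 at 29.0 against 1.43 and 2.37 TPM, and Rpl38-ps2 at 19.5 against 0 and 0 TPM. The MOD means of Stfa1 and Sprr2a2 were 21.6 and 28.5 times their CON 2 values. With the H2-Ea term the log2 differences were 4.37 for Stfa1, 4.77 for Sprr2a2 and 4.25 for Rpl38-ps2. Stfa1 and Rpl38-ps2 had the reverse of the H2-Ea pattern, above 15 TPM in CON 2 and MOD and below 1 TPM in CON 1 and CON 3. This reverse pattern was found for 3 genes, 2 of them annotated as pseudogenes. Their pooled differences thus also hold the split among the controls. All 8 genes kept their calls with the H2-Ea term (adjusted p from 0.0018 to 0.016).

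The genes with the largest fall included keratins and keratin-associated proteins of the hair shaft and inner root sheath. Krt71 fell from 2125 ± 1694 to 0.113 ± 0.0802 TPM (log2 difference -10.49, SE 0.65, limma adjusted p = 0.00053). Krt25 (log2 difference -10.40), Krt27 (-9.07), Krt73 (-8.55), Krt35 (-8.51) and S100a3 (-9.95) fell as well, S100a3 from 2667 ± 1853 to 1.31 ± 0.311 TPM. Krtap8-1 was listed at 0 in all MOD libraries, against 5502, 289 and 769 TPM in CON 1 to 3, as was Krtap7-1, against 4405, 242 and 483 TPM. All 8 kept their calls with the H2-Ea term (adjusted p from 0.0018 to 0.014).

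**Figure D2:**
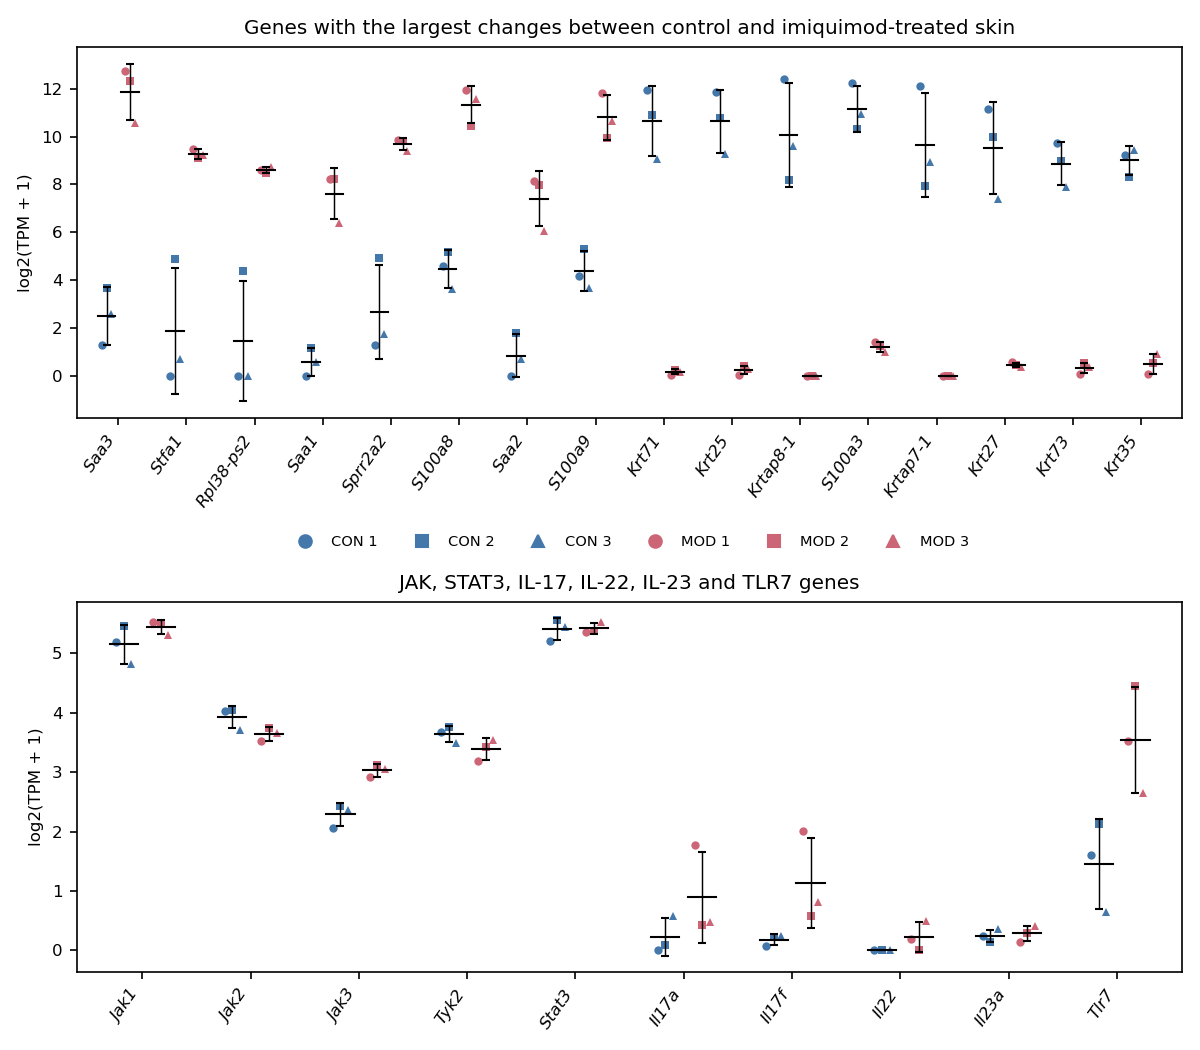
Expression per library, as log2(TPM + 1), of the 8 genes with the largest rise and the 8 with the largest fall (top) and of 10 genes of the JAK/STAT3, IL-17, IL-22, IL-23 and TLR7 pathways (bottom); bars show the mean and SD of 3 libraries per group. Saa3 reached 1494 to 6929 TPM in MOD, and Stat3 lay between 36.1 and 46.3 TPM in all 6 libraries.

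Camera put 29 of the 38 lists past the threshold, 23 higher and 6 lower, relative to other genes. With estimated inter-gene correlations 0 passed (6 had an unadjusted p below 0.05), while fry passed 17. Other ways of splitting the same 6 libraries gave up to 26 lists past the camera threshold. Those splits keep part of the difference between CON and MOD, so 26 is not a chance rate. Because 0 lists passed with estimated correlations, list results below rest on their counts of genes. Camera values are given with both correlations. Among all 15323 tested genes 1914 rose and 5538 fell (48.6% changed). A count near these shares says little about the list itself.

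Neutrophil genes rose. Of 19 markers found 12 met the expression filter, and all 12 passed (12 adjusted over the list alone, 11 with the H2-Ea term), with a median log2 difference of 3.69 (camera adjusted p = 2.6e-12, adjusted p = 0.30 with an estimated correlation). Stfa2l1 rose from 1.62, 2.79 and 0 TPM in CON to 119 ± 63.7 TPM. Retnlg, which encodes a neutrophil resistin-like protein, was listed at 0 in all controls and at 59.6, 11.5 and 17.4 TPM in MOD. Markers near 0 in CON met the filter through MOD and could hardly have fallen, so the count of 12 leans towards a rise. Of 18 antimicrobial and alarmin genes 11 rose and 1 fell (12 and 2 adjusted over the list alone, 11 and 1 with the H2-Ea term; camera adjusted p = 5.5e-08, adjusted p = 0.22 with an estimated correlation). The 1 that fell was Defb6, a beta-defensin, from 1697 ± 282 to 428 ± 214 TPM. Of 23 chemokines 7 rose and 2 fell (7 and 2 adjusted over the list alone, 2 and 2 with the H2-Ea term; camera adjusted p = 0.00043, adjusted p = 0.38 with an estimated correlation). Cxcl2, a neutrophil attractant, was at 0 to 0.31 TPM in CON and at 152, 9.35 and 33.1 TPM in MOD. Ccl3 was at 0.10, 0.60 and 0.20 TPM in CON and at 39.8, 5.66 and 15.3 TPM in MOD, and Cxcl14, a chemokine of resting epidermis, fell from 151 ± 10.3 to 26.9 ± 2.75 TPM. Of 14 IL-1 and IL-36 family genes 3 rose and 1 fell (2 and 1 adjusted over the list alone). Il1b rose from 2.62 ± 0.387 to 57.4 ± 57.1 TPM and Il36g from 4.84 ± 3.03 to 22.5 ± 3.22 TPM, but neither passed with the H2-Ea term (adjusted p = 0.052 and 0.064, the highest of their alternatives, from 0.0049 and 0.0039). The list's camera call (adjusted p = 0.014, adjusted p = 0.53 with an estimated correlation) was lost without CON 3 (adjusted p = 0.10) and with the H2-Ea term (adjusted p = 0.27, in a range of 0.0024 to 0.27 over the alternatives), where 0 rose and 2 fell and the median turned from 0.38 to -0.23.

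The cytokines of the IL-23/IL-17/IL-22 axis were low. Il17a stood at 0, 0.07 and 0.50 TPM in CON and 2.44, 0.34 and 0.39 TPM in MOD, and Il17f at 0.05, 0.17 and 0.18 against 3.01, 0.50 and 0.77 TPM. Il22 was listed at 0 in CON and at 0.14, 0 and 0.41 TPM in MOD, and Il23a at 0.11 to 0.28 TPM in CON and 0.11 to 0.33 TPM in MOD. None of these 4 met the expression filter, so they were not tested. Of the 10 tested genes of this axis 3 rose and 4 fell (3 and 4 adjusted over the list alone, 0 and 2 with the H2-Ea term). The IL-22 receptor gene Il22ra1 fell from 4.18 ± 2.50 to 0.347 ± 0.145 TPM and Il17re from 10.9 ± 1.25 to 4.26 ± 0.347 TPM. Il10rb went the other way, from 19.3 ± 5.48 to 41.0 ± 0.574 TPM (log2 difference 1.08, or 0.68 with the H2-Ea term). The list was not past the threshold (camera adjusted p = 0.38, direction up), while its median was -0.02 and its mean -0.24. The median was positive under the 3 other scalings and with the H2-Ea term (0.14).

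Stat3, Jak1, Jak2 and Tyk2 did not pass limma's threshold. Members of the list of STAT3 targets and gp130 receptors changed in both directions, with camera's direction up. These are mRNA levels. Phosphorylation of the proteins was not measured, so the values do not show whether JAK/STAT3 signalling was active. Stat3 was at 41.7 ± 5.18 TPM in CON and 41.9 ± 2.77 TPM in MOD (log2 difference 0.01, SE 0.14, limma adjusted p = 0.95). It passed only under median-of-ratios scaling (0.36, adjusted p = 0.046, in a range of 0.046 to 0.99 over the alternatives). Jak1 (log2 difference 0.29, adjusted p = 0.23), Jak2 (-0.29, adjusted p = 0.15) and Tyk2 (-0.25, adjusted p = 0.22) did not pass; Jak1 passed under median-of-ratios and quantile scaling (adjusted p = 0.029 and 0.034, in a range of 0.029 to 0.96), and Jak2 and Tyk2 turned slightly positive there. Jak3, a kinase of lymphoid cells, rose from 3.92 ± 0.639 to 7.19 ± 0.613 TPM (log2 difference 0.74, adjusted p = 0.011; 0.11 with the H2-Ea term, the highest in a range from 0.0033). It was the 1 riser among 10 tested JAK and STAT genes (1 adjusted over the list alone, 0 with the H2-Ea term), and the list was not past the threshold (camera adjusted p = 0.068). It passed under 6 of the 19 alternatives, among them all 3 other scalings and leaving out CON 2 or MOD 1 (adjusted p from 0.0058 to 0.28 over all of them). Its median turned from 0.03 to -0.14 with the H2-Ea term. Of 26 STAT3 targets and gp130 receptors 7 rose and 8 fell (8 and 8 adjusted over the list alone, 2 and 4 with the H2-Ea term). Timp1, an inhibitor of metalloproteinases, rose from 11.8 ± 1.69 to 55.4 ± 9.47 TPM and Ccnd1, cyclin D1, fell from 86.5 ± 11.1 to 14.3 ± 6.43 TPM. The list's camera call (adjusted p = 0.019, adjusted p = 0.53 with an estimated correlation) was lost under 4 alternatives, among them without CON 3 (adjusted p = 0.060) and with the H2-Ea term (adjusted p = 0.089, the highest in a range from 0.011), where its median turned from 0.12 to -0.09. Among 22 TLR7 signalling genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, 1 and 1 with the H2-Ea term), with a median of -0.03, a mean of 0.17 and no camera call (adjusted p = 0.071). It passed without MOD 1 (adjusted p = 0.049) and under the 3 other scalings (adjusted p from 0.015 to 0.046), in a range of 0.015 to 0.23 over the alternatives. Tlr7, the receptor of imiquimod, was at 1.98 ± 1.40 TPM in CON and 12.2 ± 7.90 TPM in MOD (log2 difference 2.09, adjusted p = 0.018). The call was lost without MOD 1 (adjusted p = 0.057), without the filter on low values (adjusted p = 0.053) and with the H2-Ea term (adjusted p = 0.17, the highest in a range from 0.0086). Unc93b1, which carries endosomal Toll-like receptors to their compartment, rose from 28.2 ± 11.1 to 118 ± 11.3 TPM. Of 34 interferon-stimulated genes 11 rose and 0 fell (11 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 2.5e-09, adjusted p = 0.45 with an estimated correlation). Rsad2 and Bst2 had the largest rises (log2 difference 1.65 and 1.24), but 0 of the 34 passed with the H2-Ea term.

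Of 17 wound keratin and small proline-rich genes 11 rose and 3 fell (13 and 3 adjusted over the list alone, 8 and 1 with the H2-Ea term; camera adjusted p = 3.5e-07, adjusted p = 0.30 with an estimated correlation). Krt16, a keratin of wounded and psoriatic epidermis, rose 31.1-fold, from 12.1 ± 5.21 to 375 ± 36.8 TPM. Sprr2d rose from 0.73, 2.74 and 0.24 TPM in CON to 49.3 ± 18.7 TPM. Sprr1a went the other way, from 1793, 663 and 90.7 TPM in CON to 34.1 to 50.4 TPM in MOD; its limma call (adjusted p = 0.025) was lost without CON 2 (adjusted p = 0.064), without each MOD library in turn (0.066, 0.064 and 0.070), without the filter and with the H2-Ea term (from 0.0028 to 0.092 over the alternatives). All 4 tested Lce3 genes, late cornified envelope genes induced in psoriasis, rose (4 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.37 with an estimated correlation), Lce3c from 1.57 ± 2.31 to 23.4 ± 7.61 TPM. Their median was 2.77, or 2.10 with the H2-Ea term. They were low in CON, Lce3b at 0.68, 0.61 and 0 TPM. They met the expression filter through MOD and could hardly have fallen. Of 31 genes of terminal differentiation and the cornified envelope 0 rose and 5 fell (0 and 2 adjusted over the list alone, 0 and 3 with the H2-Ea term). Krt77 fell from 230 ± 196 to 1.58 ± 0.908 TPM and the desmosomal cadherin Dsg1a from 86.9 ± 50.3 to 12.9 ± 2.41 TPM. The list's median (0.29) and mean (-0.33) differed in sign, and camera, whose direction was up, made no call (adjusted p = 0.21), except without CON 2 (adjusted p = 0.026, in a range up to 0.92). With the H2-Ea term the median turned to -0.85. Of 15 basal keratinocyte and adhesion genes 1 rose and 8 fell (1 and 8 adjusted over the list alone, 0 and 7 with the H2-Ea term). Camera made no call (adjusted p = 0.20), except without the filter on low values (adjusted p = 0.018, in a range up to 0.31). Dsc3 fell from 93.5 to 159 TPM in the CON libraries to 21.9 ± 3.95 TPM and Trp63, the transcription factor p63, from 85.9 ± 3.14 to 29.4 ± 0.760 TPM. All 29 tested hair follicle genes fell in the same MOD libraries, with a median of -7.07. Krt14, the main keratin of basal cells, rose from 1554 ± 391 to 3038 ± 17.6 TPM, and did not pass with the H2-Ea term (adjusted p = 0.085, the highest in a range from 0.0044).

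Hair follicle, pigment cell and cell cycle genes fell. All 29 tested hair keratin and inner root sheath genes fell (29 adjusted over the list alone, 23 with the H2-Ea term), with a median log2 difference of -7.07, or -7.60 without the 6 genes listed at 0 throughout MOD (camera adjusted p = 1.8e-10, adjusted p = 0.38 with an estimated correlation). Members near 0 in MOD met the expression filter through CON and could hardly have risen, so the count of 29 leans towards a fall. Hair keratins and keratin-associated proteins made up 5.99, 0.838 and 0.569% of all TPM in CON 1 to 3 and at most 0.00099% in MOD. Of 12 outer root sheath and follicle stem cell genes 2 rose and 8 fell (2 and 9 adjusted over the list alone, 0 and 7 with the H2-Ea term). Krt75 fell from 173 ± 93.6 to 1.60 ± 1.46 TPM and Lhx2, a transcription factor of follicle stem cells, from 47.4 ± 12.3 to 7.44 ± 3.58 TPM. The list's camera call (adjusted p = 0.046, adjusted p = 0.50 with an estimated correlation) was lost under 4 alternatives, among them without CON 2 (adjusted p = 0.063) and without CON 3 (adjusted p = 0.056), in a range of 0.003 to 0.099. Of 10 melanocyte genes 9 fell (9 adjusted over the list alone, 5 with the H2-Ea term; camera adjusted p = 0.0060, adjusted p = 0.53 with an estimated correlation). Tyr, which encodes tyrosinase, fell from 28.8 ± 12.8 to 1.53 ± 1.63 TPM. Of 40 cell cycle genes 38 fell (38 adjusted over the list alone, 36 with the H2-Ea term), with a median of -1.49 (camera adjusted p = 2.4e-11, adjusted p = 0.38 with an estimated correlation). Mki67, a marker of proliferating cells, fell from 48.5 ± 12.4 to 11.5 ± 1.82 TPM and Uhrf1 from 58.0 ± 8.50 to 11.6 ± 2.11 TPM.

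**Figure D3:**
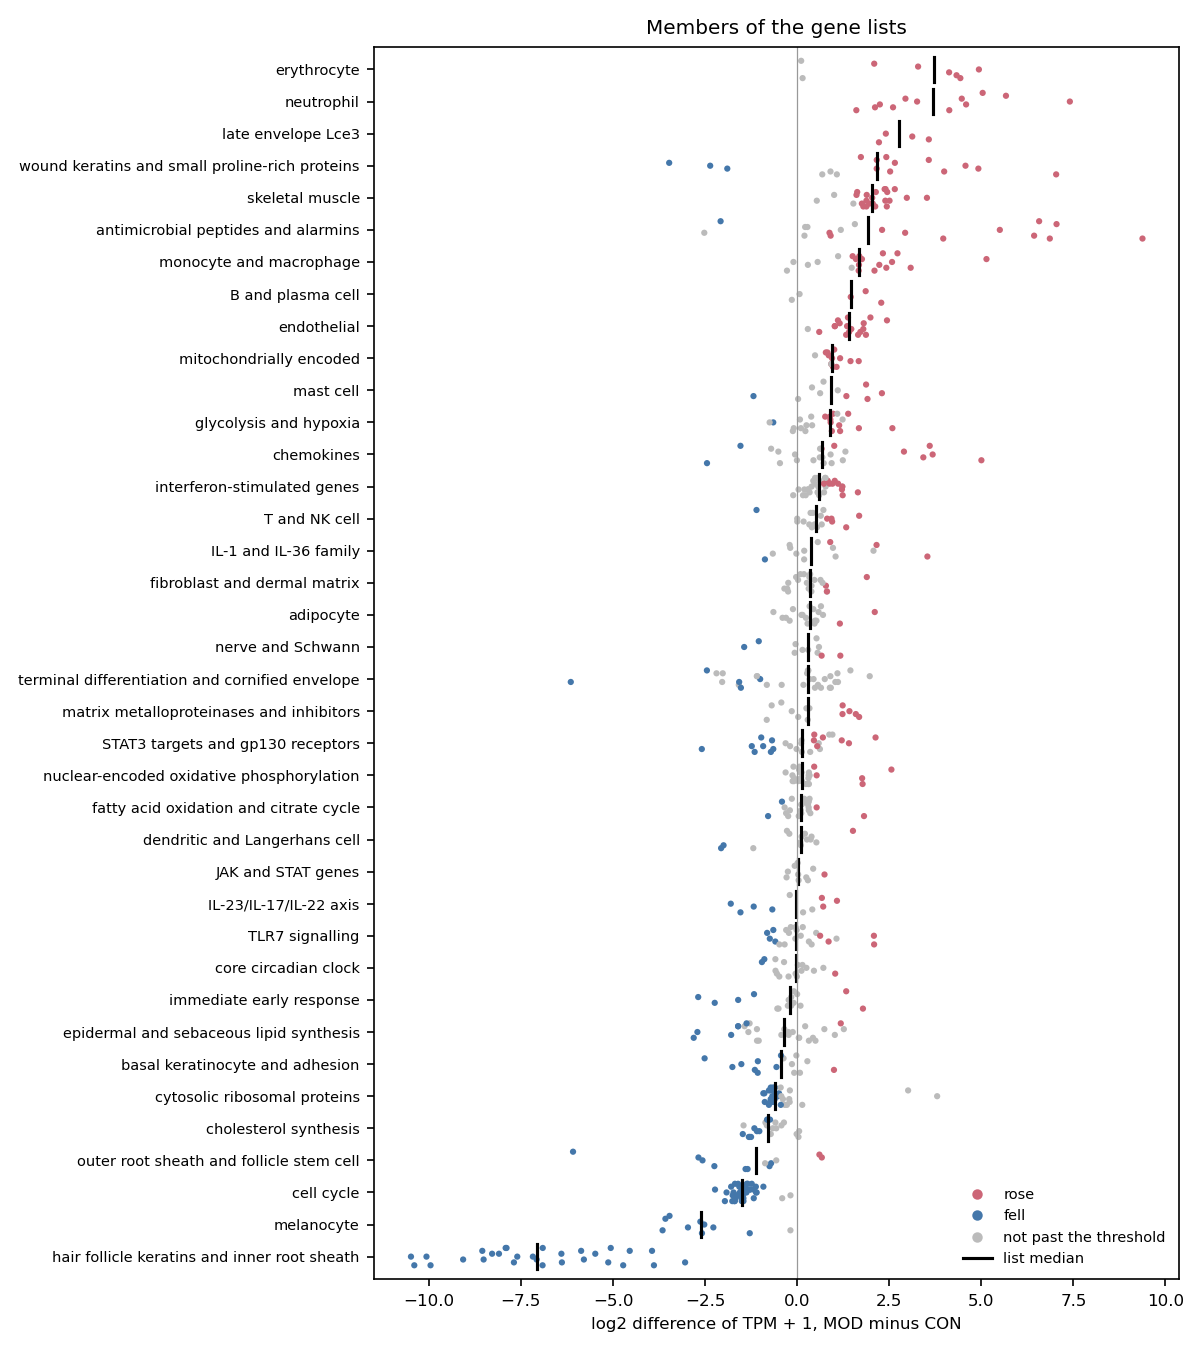
Log2 difference of TPM + 1 (MOD minus CON) of each tested member of the 38 gene lists; red points rose, blue points fell, grey points did not pass limma's threshold, and black bars are list medians. The follicle list lies lowest (median -7.07), and the erythrocyte and neutrophil lists highest (3.70 and 3.69).

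Of 20 monocyte and macrophage genes 14 rose and 0 fell (15 adjusted over the list alone, 6 with the H2-Ea term; camera adjusted p = 3.9e-09, adjusted p = 0.38 with an estimated correlation). Chil3, a chitinase-like protein of activated macrophages, rose from 0.04, 1.29 and 0.04 TPM in CON to 48.1 ± 14.5 TPM and Adgre1, the F4/80 antigen, from 10.8 ± 8.13 to 85.6 ± 22.0 TPM. Of 18 T and NK cell genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, 1 and 0 with the H2-Ea term; camera adjusted p = 5.8e-05, adjusted p = 0.49 with an estimated correlation). Trdc, the constant segment of the T cell receptor delta chain, rose from 1.35 ± 0.475 to 6.55 ± 1.41 TPM. Of 11 B and plasma cell markers found 5 met the expression filter, and 3 of these rose (3 adjusted over the list alone). The median was 1.46, or 1.89 with the H2-Ea term (camera adjusted p = 0.0049, adjusted p = 0.30 with an estimated correlation). Cd79b rose from 0.390 ± 0.178 to 6.08 ± 2.50 TPM. It was near 0 in CON, met the filter through MOD and could hardly have fallen. Of 10 mast cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, 3 and 0 with the H2-Ea term; camera adjusted p = 0.00061, adjusted p = 0.38 with an estimated correlation), the tryptase gene Tpsb2 from 19.1 ± 11.5 to 90.5 ± 21.3 TPM. Of 14 dendritic and Langerhans cell genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 2 with the H2-Ea term), with a median of 0.11, a mean of -0.15 and no camera call (adjusted p = 0.21, direction up). With the H2-Ea term the median turned to -0.26. Mgl2 fell from 44.0 ± 21.7 to 9.90 ± 4.93 TPM, and Cd86, a costimulatory molecule, rose from 4.54 ± 2.07 to 14.2 ± 1.44 TPM.

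Vessel, muscle and red cell genes rose. Of 18 endothelial genes 17 rose (17 adjusted over the list alone, 11 with the H2-Ea term), with a median of 1.40 (camera adjusted p = 8e-14, adjusted p = 0.30 with an estimated correlation). Vwf, von Willebrand factor, rose from 13.7 ± 4.89 to 76.0 ± 8.64 TPM and Emcn from 10.9 ± 0.781 to 46.6 ± 8.22 TPM. Of 24 skeletal muscle genes 21 rose (23 adjusted over the list alone, 10 with the H2-Ea term), with a median of 2.04 (camera adjusted p = 4.4e-13, adjusted p = 0.38 with an estimated correlation). The myosin light chain gene Mylpf rose from 752 ± 422 to 4325 ± 892 TPM and the myosin heavy chain gene Myh2 from 33.8 ± 27.7 to 319 ± 75.2 TPM. Of 8 erythrocyte genes 6 rose (6 adjusted over the list alone, 6 with the H2-Ea term; camera adjusted p = 6.7e-07, adjusted p = 0.37 with an estimated correlation). The globin gene Hbb-bs rose 17.1-fold, from 366 ± 131 to 6255 ± 1673 TPM. Of 22 fibroblast and dermal matrix genes 3 rose (2 adjusted over the list alone, 1 with the H2-Ea term; camera adjusted p = 0.00061, adjusted p = 0.50 with an estimated correlation). Eln, elastin, rose from 50.6 ± 20.9 to 181 ± 11.8 TPM. The list's camera call was lost with the H2-Ea term (adjusted p = 0.079, the highest in a range from 2.5e-05), where its median turned from 0.34 to -0.13. Of 13 metalloproteinases and inhibitors 5 rose (4 adjusted over the list alone, 3 with the H2-Ea term; camera adjusted p = 0.0049, adjusted p = 0.49 with an estimated correlation), Mmp3 from 21.1 ± 5.32 to 70.1 ± 19.5 TPM. The median of this list turned from 0.29 to -0.08 with the H2-Ea term. Of 19 adipocyte genes 2 rose (2 adjusted over the list alone, 0 with the H2-Ea term; camera adjusted p = 0.0020, adjusted p = 0.53 with an estimated correlation), and of 11 nerve and Schwann cell genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, 0 and 1 with the H2-Ea term). Erbb3, a receptor of Schwann cells, fell from 21.1 to 29.6 TPM in the CON libraries to 8.93 ± 1.28 TPM. The nerve list's camera call (adjusted p = 0.048, adjusted p = 0.53 with an estimated correlation) was lost under 10 of the 19 alternatives (adjusted p from 0.024 to 0.18), among them without CON 1, CON 3 or MOD 3 (adjusted p = 0.080, 0.084 and 0.14).

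Beside the metabolic lists, 21 of 24 skeletal muscle genes rose in the same MOD libraries, with a median of 2.04. Mitochondrially encoded genes took 10.7 to 13.2% of MOD values and 6.58 to 7.32% of CON values, and 11 of 13 rose (12 adjusted over the list alone, 5 with the H2-Ea term; camera adjusted p = 7.7e-08, adjusted p = 0.30 with an estimated correlation). mt-Nd3 rose from 575 ± 110 to 1627 ± 617 TPM, but not with the H2-Ea term (adjusted p = 0.085, the highest in a range from 0.0053). Of 27 nuclear-encoded oxidative phosphorylation genes 5 rose (3 adjusted over the list alone, 1 with the H2-Ea term; camera adjusted p = 0.00030, adjusted p = 0.53 with an estimated correlation). The largest changes were in Cox6a2, Cox7a1 and Cox8b, whose products are the muscle isoforms of cytochrome c oxidase subunits (log2 difference 2.56, 1.78 and 1.76). Only Cox7a1 of these passed with the H2-Ea term (adjusted p = 0.043, the others 0.066 and 0.050). Of 22 fatty acid oxidation and citrate cycle genes 2 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 0 with the H2-Ea term), led by Cpt1b, the muscle form of carnitine palmitoyltransferase (8.08 ± 4.69 to 28.7 ± 5.24 TPM). The camera call (adjusted p = 0.019, adjusted p = 0.53 with an estimated correlation) was lost without CON 2 (adjusted p = 0.050) and without MOD 1 (adjusted p = 0.079, the highest in a range from 0.00084). Of 23 glycolysis and hypoxia genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, 2 and 0 with the H2-Ea term; camera adjusted p = 1e-06, adjusted p = 0.38 with an estimated correlation), the lactate transporter gene Slc16a3 from 7.88 ± 3.79 to 51.0 ± 15.5 TPM.

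Of 22 cholesterol synthesis genes 10 fell and 0 rose (11 adjusted over the list alone, 4 with the H2-Ea term), Sqle from 76.4 ± 7.14 to 28.5 ± 13.3 TPM. The list's camera call (adjusted p = 0.048, adjusted p = 0.64 with an estimated correlation) was lost under 9 of the 19 alternatives (adjusted p from 0.0002 to 0.26), among them without CON 2, CON 3, MOD 1 or MOD 3 (adjusted p = 0.089, 0.13, 0.060 and 0.14). Of 27 epidermal and sebaceous lipid genes 1 rose and 6 fell (1 and 3 adjusted over the list alone, 0 and 2 with the H2-Ea term), and camera made no call (adjusted p = 0.70), with a direction opposite to the median of -0.35. Awat2, a wax ester synthase of sebaceous glands, fell from 23.9 to 43.6 TPM in the CON libraries to 5.08 ± 3.23 TPM. Of 29 cytosolic ribosomal protein genes 0 rose and 18 fell (18 adjusted over the list alone, 10 with the H2-Ea term), with a median of -0.60, or -0.24 with median-of-ratios scaling. Rpl7 fell from 1726 ± 77.6 to 915 ± 98.4 TPM and Rps3 from 2124 ± 142 to 1147 ± 90.3 TPM. The list's camera call (adjusted p = 0.016, adjusted p = 0.57 with an estimated correlation) was lost with median-of-ratios scaling (adjusted p = 0.058), without CON 2 (adjusted p = 0.13) and without CON 3 (adjusted p = 0.062), in a range from 0.00015 to 0.13. Of 17 core clock genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 1 with the H2-Ea term; camera adjusted p = 0.44, direction up against a median of -0.04), Cry1 from 9.36 ± 1.82 to 4.56 ± 0.762 TPM. Of 16 immediate early genes 2 rose and 4 fell (2 and 4 adjusted over the list alone, 1 and 7 with the H2-Ea term; camera adjusted p = 0.78, with a direction opposite to the median of -0.20). Egr3 fell from 56.6 ± 5.98 to 8.15 ± 2.41 TPM and Egr1 from 64.6 ± 32.3 to 12.9 ± 6.63 TPM. The medians of the clock, immediate early, lipid and TLR7 lists turned positive under median-of-ratios scaling.

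Among genes at least 2-fold higher, 202 Gene Ontology and 37 KEGG terms were over-represented (Fisher's exact test, adjusted p below 0.05). Fisher's test treats genes as independent, so its p-values do not measure the spread between libraries and are too low where genes move together. For the skeletal muscle list, camera's adjusted p went from 4.4e-13 to 0.38 with an estimated correlation. The terms rest on the calls of the pooled fit. The lowest p was for the muscle Z disc (47 of 119 genes, 8.75 by chance, adjusted p = 1.2e-19), with Myoz2, Actn2 and Xirp2 changing most. Next came skeletal muscle tissue development (27 of 45, adjusted p = 1.2e-16), with Ankrd1, Ankrd2 and Myoz2, and inflammatory response (52 of 189, adjusted p = 2.3e-14), with Chil3, Cxcl2 and Krt16. Ankrd1, a stress-induced ankyrin repeat protein of muscle, rose from 0.410 ± 0.330 to 45.1 ± 27.7 TPM and Ankrd2 from 7.04 ± 3.89 to 178 ± 88.8 TPM. Among genes at least 2-fold lower, 110 Gene Ontology and 23 KEGG terms passed. The lowest p values were for keratin filament (39 of 54, adjusted p = 4.5e-19), intermediate filament (38 of 63, adjusted p = 1.2e-14) and cell division (85 of 290, adjusted p = 2e-09), and in KEGG by the cell cycle (47 of 121, adjusted p = 4.6e-10).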

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

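The fit with the H2-Ea term was chosen after the data were examined, and the other alternatives before. Estimated inter-gene correlations, fry and treat apart, none of the 38 lists and 152 tested genes of the naming rule reversed a call under an alternative. Under all of those run on them, 26 lists and 91 genes kept their side of the threshold. With at least 5 TPM in 3 libraries 36 lists and 137 genes could be run, and without the 20 most abundant genes 150 genes. The H2-Ea term ended the largest number of gene calls (53). Jak1, Jak2, Tyk2 and Stat3 had no call to lose. Against 7452 genes changed, 4862 to 7216 changed when a library was left out (4816 to 6506 of the 7452 among them), 3414 with the H2-Ea term (3300 of the 7452) and 329 under treat, which tests for a log2 difference above 1 (94 higher and 235 lower). Leaving out a library gave 1303 to 2025 higher and 3559 to 5487 lower genes, 905 to 1360 and 1693 to 2313 at least 2-fold, and 23 to 29 lists. The lowest total and the 3559 came without MOD 1. Higher genes numbered 3097 with median-of-ratios scaling and 667 with the H2-Ea term. Lower genes numbered 2868 with median-of-ratios scaling, 3177 with quantile normalization and 2747 with the H2-Ea term. At least 2-fold higher genes numbered 1737 with median-of-ratios scaling and 571 with the H2-Ea term, and at least 2-fold lower genes 1052 with median-of-ratios scaling and 1138 with quantile normalization. Both scalings move the centre of all genes from -0.31 towards 0 by construction, and the H2-Ea term leaves 1 control in the contrast. For the other changes the cause was not tested. For lists, 0 passed with estimated inter-gene correlations and 17 under fry. Terms among lower genes numbered 303 without the fold threshold, where more genes enter.

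With the replicate number as a block, 7257 genes changed and the TLR7 signalling list passed, but samples share only a number. Deviations from the group means, across genes, correlated at 0.00462, 0.0685 and 0.0656 for same-numbered pairs, and CON 1 correlated best with MOD 2. Of the calls without the block, 6765 were shared. Sequencing depth is unknown, so what it limits cannot be stated. On simulated data 50% of genes changed by 1 on the log2 scale were recovered. Only 200 genes were changed there, so this share does not carry over to the data.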

Other observations

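The tests in this part were chosen after the result was seen, except the annotation terms, the counts of changed genes over other splits, the follicle median without CON 1 and the muscle medians under other scalings.

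Enriched terms covered further gene groups. Their p-values, too, come from a test that treats genes as independent. Among genes at least 2-fold higher, complement and coagulation cascades (21 of 47 genes, 3.88 by chance, Fisher's exact test, adjusted p = 3.1e-09) were represented by Itgam, an integrin of myeloid cells, which rose from 6.18 ± 3.96 to 36.2 ± 1.80 TPM, by Vwf and by the complement gene C1qb, which rose from 98.3 ± 78.6 to 432 ± 66.7 TPM but did not pass with the H2-Ea term (limma adjusted p = 0.059). The Staphylococcus aureus infection term (22 of 62, adjusted p = 1.2e-07) held Krt16, the beta-defensin gene Defb14 (9.16, 0 and 12.8 TPM in CON 1 to 3, 80.7 ± 11.2 TPM in MOD) and the Fc receptor gene Fcgr4 (1.30 ± 0.834 to 22.7 ± 6.40 TPM). The term was also over-represented among lower genes (19 of 62, adjusted p = 0.0085), through keratins such as Krt25, Krt27 and Krt35. Among genes at least 2-fold lower, Wnt signalling (44 of 148, 19.9 by chance, adjusted p = 9.7e-06) was led by Lef1, a transcription factor of the pathway (49.4 ± 12.5 to 2.69 ± 2.14 TPM), the receptor gene Fzd10 (31.1 to 38.1 TPM in the CON libraries, 3.02 ± 0.270 TPM in MOD) and Wnt10b (21.8 ± 6.55 to 1.93 ± 0.967 TPM). In the same MOD libraries all 29 tested hair follicle genes fell (median -7.07). Bicellular tight junction (33 of 94, adjusted p = 3.8e-05) held Cldn4 (82.6 ± 41.9 to 5.97 ± 2.49 TPM), Ocln, which encodes occludin (12.9 ± 5.15 to 1.21 ± 0.372 TPM), and Cldn3 (7.34 ± 2.86 to 0.403 ± 0.0839 TPM).

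The real grouping changed 7452 genes, and the highest of the other 9 ways to part the 6 libraries 3 against 3 changed 3. The real grouping was the 1 of 10 with that many. For lists, the real grouping gave 29 past the camera threshold and the highest other 26, again 1 of 10 with that many. With 10 splits no share under 0.05 can be reached. Each of the other 9 splits mixes CON and MOD libraries in unequal numbers. Part of the difference between CON and MOD stays in such a contrast, and the rest adds to the residual spread. Their counts of genes and lists are therefore not chance rates.

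CON 1 and CON 3 shared 39 genes above 15 TPM that were below 1 TPM in CON 2 and all MOD libraries, among them H2-Ea, Ahcyl (122 and 113 TPM) and Rpl3-ps1 (1209 and 1328 TPM). A library from an imiquimod-treated animal under the label CON 2 is argued against, since the hair follicle list had a median log2 difference of -5.89 between MOD and CON 2. A candidate explanation is that the mice differed in strain or MHC haplotype, which would let reads that differ from the reference land on retrocopies: pseudogenes made up 81.1% of the typed genes of the pattern, 31.6 times their share among tested genes, and for 14 copies with a parent gene known by name the median log2 of CON 1 and CON 3 over CON 2 went from -0.59 for the parent (lower for 11 of 14) to 0.27 for the sum of copy and parent, but the sums did not balance for Rps18 (-3.78 and -3.51 with either copy), Tma7 (2.35), Itpa (1.11) and Glo1 (1.04), so an exchange of reads with the named copy does not account for these. A library or processing batch that parts the same libraries cannot be told apart from this by the pseudogenes. Of those, 82 others were above 15 TPM in all 6 libraries, which neither excludes nor needs a batch. H2-Ea, typed as a polymorphic pseudogene, was listed at 0 in CON 2 and MOD. There H2-Eb1, H2-Aa, H2-Ab1 and Cd74 stood at 194 to 1090 TPM. The class II genes were thus not lowered together, though this rests on 1 gene. Neither strain nor batch is given in the sources used here. If strain differed, 2 of 3 controls would differ from MOD in more than the treatment, and the fit with the H2-Ea term, with 3414 genes, is the comparison it leaves.

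Hair keratin and inner root sheath genes had a median log2 difference of -7.07. A lower share of keratinocytes is argued against as the whole cause, since the basal keratinocyte list had a median of -0.44 (SD of members 0.90). The fall did not rest on CON 1, the control with the most follicle transcripts, since the median without it was -5.95. Growing follicles in the controls and resting ones in MOD at sampling may also part the groups; the cell cycle list fell with the follicle list (median -1.49), but a hair cycle stage shared by a group's animals cannot be told apart from imiquimod here. Whether imiquimod itself ended hair growth stays open and was not tested.

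Skeletal muscle genes were higher in MOD by a median of 2.04. A lower follicle and epidermal share that raised all other tissues alike is argued against, since the muscle median lay 1.70 above those of the fibroblast and adipocyte lists (SD of muscle members 0.61). Under the 3 other scalings the lowest muscle median was 2.14. All tested genes centred at -0.31, so these scalings tend to raise lists in MOD and could hardly have lowered it. The rise was thus present under each scaling, but these values could not have excluded scaling to the library total as a cause. More of the muscle layer under the skin in the MOD pieces may account for it; 22 of 24 muscle genes were higher in every MOD library than in every CON library, among them the abundant Mylpf, but the labels give no depth of dissection, and this cannot be told apart from a response of the muscle to imiquimod.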
